A study of Arabidopsis thaliana with 12 samples.

How the data were processed

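Total RNA of Arabidopsis thaliana was profiled on 12 arrays, 6 from plants given water and then staurosporine and 6 from plants given staurosporine and then ascorbate, with groups and replicate numbers taken from the labels. The deposited values were intensities on a linear scale from 0 to 100, with no missing value, and what they are relative to, the scanner, the background correction and any normalization are not given in the sources used here. Array medians of the deposited log2 intensity spanned 1.53, above the limit of 0.2 set before the data were examined, and the values were therefore quantile-normalized between arrays. Zeros were set to the smallest positive value of their array before log2 was taken. A value of 0 may be a failed reading, since 112 features, among them the Calvin cycle gene SBPASE, were listed at 0 on all 12 arrays. The smallest positive value differed between arrays, so before normalization such features differ between the groups with no reading behind it.

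Probes were named through the platform annotation and current symbols of the TAIR10.1 annotation, used for names only. Of 692 probes with 1 gene, 690 matched by Entrez number, and 2 did not. Probes of 1 locus were averaged, which left 3438 features and 690 named loci. RIQ2, PYG7, AEF1, CLPS1, HISN4 and similar symbols that the annotation lacks were assigned by locus. The number of arrays, 6 per group, limits the precision.

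Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p under 0.05), as ascorbate minus staurosporine with no block, and all adjusted p-values of single genes are limma's. Gene lists of at least 5 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Only 1 of the 22 fixed lists reached that size. Named genes were the 8 largest rises and the 8 largest falls among genes that passed, the 2 members of each fixed list with the smallest p, and a fixed set of antioxidant genes, of which PRXIIE was measured. Genes without zeros and genes in lists assembled later were added after their values were seen.

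Deviations from the group mean correlated across features between same-numbered arrays of the groups, at 0.184, 0.182, 0.315, 0.347, 0.106 and 0.157 for numbers 1 to 6. Each was above 0.1, so the numbers were taken as pairing the arrays, from the data and not from the labels. Of the 6 staurosporine arrays, 5 correlated best with the ascorbate array of their own number, and number 5 did not. Arrays with consecutive numbers (1 and 2, 3 and 4, 5 and 6) had Spearman correlations of 0.889 to 0.983 within a group, each the highest of its array within the group. Pair averages, with 3 values per group, are therefore given beside the planned fit, as planned before the data were examined. The correlation between consecutive arrays estimated by duplicateCorrelation was 0.54.

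The fit was tested on simulated data with 200 changed features among 3438, 50 at each size. The changed features were drawn from those with no zero. The simulation had no floor, no scale difference between arrays and no pairing across groups, so its rates do not cover genes listed at 0. With independent arrays it recovered 5, 28, 47 and 47 of 50 at log2 changes of 0.5, 1, 2 and 3, with 4 false calls. With consecutive arrays correlated, the 12-array fit made 67 false calls and pair averages 3, and pair averages recovered 0, 1, 29 and 44 of 50. Alternatives were the deposited scale, median centring, cyclic loess, a pseudocount of 0.0438 in place of the floor, removal of the dimmest 25% of features, the array number as a block, consecutive arrays as a random block, an intensity trend with a robust prior, array weights and each array left out. No coordinates are printed, since no genome build is given in the sources used here.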

Results

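RNA from wild-type Arabidopsis thaliana plants of the Columbia ecotype was measured on 12 arrays of 3439 probes each, in 2 groups of 6. Staurosporine is a broad inhibitor of protein kinases, and ascorbate (vitamin C) is the main water-soluble antioxidant of plant cells. Per the labels, plants of the staurosporine group were kept in water for 4 h and then in staurosporine for 4 h. Plants of the ascorbate group received staurosporine for 4 h and then 25 mM ascorbate for 4 h. A pH of 5.5 is given for both groups. The groups thus differed in the timing of staurosporine as well as in ascorbate. The labels give 2 µM staurosporine for the ascorbate group and 25 mM for the staurosporine group. The 25 mM given for staurosporine equals the ascorbate dose and may be a slip in the label, so whether the staurosporine dose differed is not known. The deposited intensities ran from 0 to 100 in relative units, with array medians between 0.169 and 0.486 and exact zeros on 10.3% to 17.3% of probes. Of the probes, 692 were listed with 1 gene, 870 with several and 1877 with none, and only the first kind is named here. Array pairs with consecutive numbers resembled each other, so levels are given as the mean ± SD of 3 pair averages per group. Levels are deposited intensities, while log2 changes and p-values come from quantile-normalized values, so the ratio of 2 levels need not match the log2 change and can differ from it in direction.

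**Figure D1:**
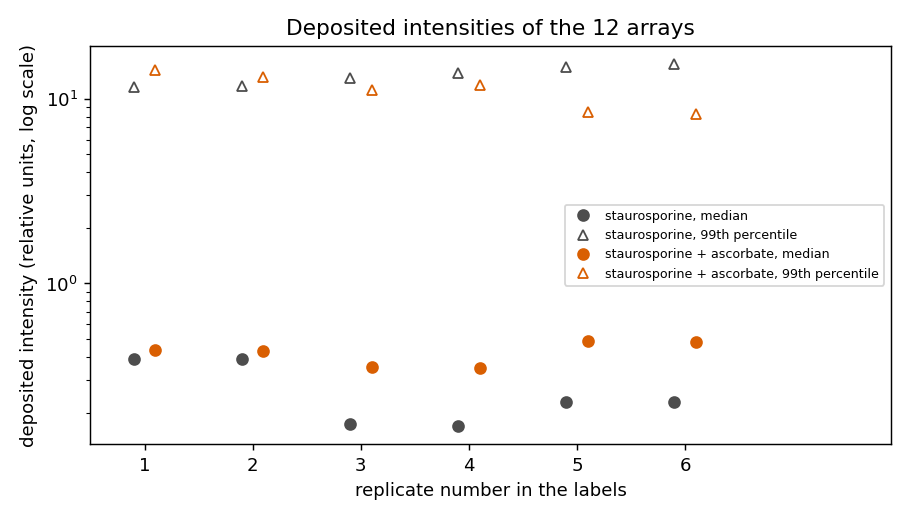
Deposited intensity of each array on a log axis, by the replicate number in the labels (horizontal axis); filled circles are array medians and open triangles the 99th percentiles, grey for staurosporine and orange for staurosporine then ascorbate. Medians of the arrays numbered 3 and 4 were 0.173 and 0.169 with staurosporine and 0.355 and 0.351 with ascorbate, and those of the arrays numbered 1 lay closer, at 0.392 and 0.437.

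The comparison asked which transcripts differed when ascorbate followed staurosporine. CYN (AT3G23490), the cyanase that breaks down cyanate, fell from 4.21 ± 0.875 to 0.93 ± 0.174 (SD, n = 3 pair averages), a log2 change of −2.08 ± 0.13 (SE). HISN4, listed as AT-HF (AT4G26900), an enzyme of histidine synthesis in plastids, fell from 1.72 ± 0.37 to 0.405 ± 0.0849. AT3G06200 fell from 5.88 ± 1.34 to 1.37 ± 0.167, and AT4G31210 from 0.643 ± 0.247 to 0.252 ± 0.0593. Each of the 4 was lower in all 3 pairs, on each scale tried and without any 1 array. A same sign in all 3 pairs was common, in 930 of 966 called and 703 of 2472 uncalled features, and adds little to a call. For these 4, limma adjusted p-values over the 12 arrays were 8.2e-06, 9.0e-05, 3.1e-05 and 0.000411, and 0.039, 0.0465, 0.0472 and 0.0472 over pair averages. With the pair as a block in the fit of pair averages, none of the 4 passed (adjusted p = 0.196 for each).

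The other genes among the 8 largest falls were dimmer. AEF1 (AT3G22150), a pentatricopeptide repeat protein that acts in organelle RNA editing, fell by 2.42 on the log2 scale (SE 0.59, adjusted p = 0.012, 0.0625 over pair averages), but by 0.92 on the deposited scale (adjusted p = 0.259). AT1G24040 had a log2 change of −2.56 (SE 0.74, adjusted p = 0.0261), with an adjusted p of 0.0738 when the array number was a block and 0.199 over pair averages. Its change was −0.96, −1.68 and −5.04 in the 3 pairs, and −1.35 on the deposited scale (limma adjusted p = 0.00875). Its call was lost when any of 3 single arrays was left out. FATB (AT1G08510), the plastid thioesterase that releases saturated fatty acids, read 0.138 to 0.362 on the staurosporine arrays and 0 to 0.287 on the ascorbate arrays, with 1 array at 0 (adjusted p = 0.0285, 0.039 over pair averages, 0.106 on the deposited scale). The FATB call was lost without any of 6 single arrays. Its normalized log2 readings differed widely within ascorbate pairs, at −1.95 and −12.55 on arrays 3 and 4, and −3.78 and −10.03 on arrays 5 and 6. The p over pair averages does not take up that spread. The size of these falls depended in part on the normalization. FATB read 0.0506 on ascorbate array 6, above its 0.0421 and 0.027 on ascorbate arrays 1 and 2. After normalization the order was reversed, at −10.03 against −7.01 and −7.70. At a reading of 0.113, AT1G24040 became −6.70 on ascorbate array 6 and AEF1 −3.89 on ascorbate array 1. Like dim readings thus took unlike normalized values on different arrays. AT5G27560 read 0.0796 to 0.204 and 0 to 0.14, also with 1 ascorbate array at 0 (adjusted p = 0.0133, 0.0878 over pair averages and 0.193 on the deposited scale).

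The 8 largest rises were all in genes listed at 0 on several staurosporine arrays, so no fold is given for them. AT4G05070 was listed at 0 on 4 of 6 staurosporine arrays and read 0.94 to 1.89 on the ascorbate arrays (adjusted p = 0.00876, 0.173 over pair averages). AT1G56460 was listed at 0 on 5 staurosporine arrays and read 0.0797 to 0.331 with ascorbate (adjusted p = 0.000476, 0.0472 over pair averages). AT1G29070, which encodes a plastid ribosomal protein of the large subunit, was listed at 0 on all 6 staurosporine arrays and on 1 ascorbate array, and reached 0.604 (adjusted p = 0.0077, 0.1 over pair averages). AT4G05030, listed at 0 on 3 staurosporine arrays, read 0.126 to 0.606 with ascorbate (adjusted p = 0.00511, 0.0751 over pair averages). AT4G37420, AT1G58230, AT1G11820 and GH9B8 (a family 9 glycosyl hydrolase, a family that includes cellulases) completed the 8, with adjusted p-values of 0.032, 0.0253, 0.0355 and 0.0403. With the array number as a block these 4 had adjusted p-values of 0.0512, 0.0519, 0.0592 and 0.068, and 0.183 to 0.264 over pair averages. Calls for AT4G37420, AT1G11820 and GH9B8 were lost without any of 10, 9 and 10 single arrays. AT4G37420 read 0.175 and 0.234 on staurosporine arrays 1 and 2, within its range of 0.162 to 0.304 on the ascorbate arrays. Its rise thus rests on the 4 staurosporine arrays listed at 0, and its log2 change in the pair of arrays 1 and 2 was 0.33.

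Genes with no zero on any array were looked at after the values were seen. The largest log2 rises among named ones were AT4G18540 (2.33, adjusted p = 0.00795, 0.127 over pair averages), the MADS-box gene AGL54 (from a level of 0.243 ± 0.279 to 0.998 ± 0.346, adjusted p = 0.014, 0.0686 with the array number as a block, 0.173 over pair averages) and AT3G52550 (1.95, adjusted p = 0.00483, 0.142 over pair averages). In the pair of arrays 1 and 2 the log2 changes of AT4G18540, AGL54 and AT3G52550 were smaller, at 0.78, 0.16 and 0.64. The others given here were chosen from the next ones by what is known of them or by their p. RIQ2 (AT1G74730), a thylakoid protein that affects the organisation of grana and light-harvesting complexes, rose from 0.147 ± 0.0693 to 0.703 ± 0.135, a log2 change of 1.68 ± 0.17 (SE, limma adjusted p = 7.1e-05, 0.0445 over pair averages, 0.196 with the pair as a block). PIFI (AT3G15840), which is linked to electron flow into the plastoquinone pool, rose from 0.248 ± 0.239 to 0.973 ± 0.188 (log2 change 1.79, adjusted p = 0.00175, 0.101 over pair averages). AT1G68660, which encodes CLPS1, an adaptor of the plastid Clp protease, rose from 0.105 ± 0.0892 to 0.51 ± 0.107 (log2 change 1.88, adjusted p = 0.00483, 0.0724 over pair averages). AT4G30740 rose from 0.207 ± 0.174 to 0.895 ± 0.0777 (log2 change 1.81, adjusted p = 0.000266, 0.0714 over pair averages). RIQ2, PIFI, AT1G68660 and AT4G30740 were higher in all 3 pairs and on each scale tried. A same sign in all 3 pairs was common among called features, as given above, and adds little for genes chosen after their values were seen.

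**Figure D2:**
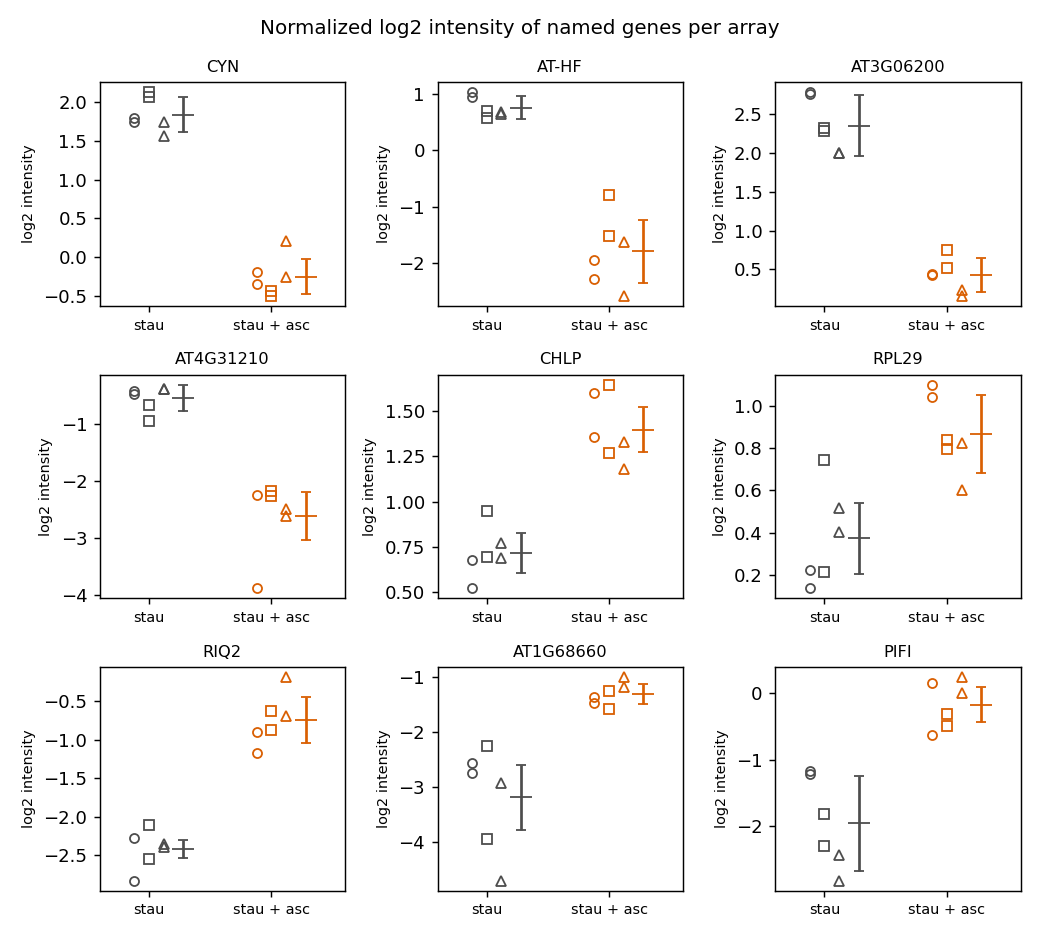
Quantile-normalized log2 intensity (vertical axes) of 9 named genes on each array of the staurosporine (stau, grey) and staurosporine then ascorbate (stau + asc, orange) groups; circles, squares and triangles mark the pairs of arrays numbered 1 and 2, 3 and 4, and 5 and 6, and bars show the mean ± SD of the 3 pair averages. CYN lay between 1.56 and 2.12 with staurosporine and between −0.49 and 0.21 with ascorbate; the rises of CHLP and RPL29 turned to −0.21 and −0.30 after median centring.

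The gene lists fixed before the data were examined held 393 loci, of which 20 had a single-gene probe, so that most of the chloroplast and antioxidant genes of interest were not analysed here. The fixed list of plastid ribosomal proteins had 5 measured members and did not hold AT1G29070, described above. Of the 5, RPL29 rose (log2 change 0.49 ± 0.12 SE, adjusted p = 0.0123), RPS10 fell (−0.81 ± 0.26 SE, adjusted p = 0.0404), and RPL5, RPL17 and RPS6 did not pass. Over pair averages RPL29 and RPS10 had adjusted p-values of 0.153 and 0.15. RPL29 turned to −0.30 after median centring and had an adjusted p of 0.0543 with the array number as a block, while RPS10 turned to 0.17 on the deposited scale and was lost without any of 8 single arrays. The list was not shifted relative to other genes (camera p = 0.763, and p = 0.766 with an estimated correlation), and its median change of 0.10 and mean of −0.32 differed in sign. With limma, fry gave an adjusted p = 0.649 for a common direction and an adjusted p = 0.0315 for change in either direction (0.000793 over pair averages). Since 205 of the 690 named genes passed, a small value for change in either direction says nothing particular to this list. Adjusted over the list alone, 2 of the 5 passed, the same number as over all genes.

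In tetrapyrrole synthesis, CHLP (AT1G74470), the geranylgeranyl reductase that supplies the phytyl chain of chlorophyll, rose from 1.69 ± 0.122 to 2.53 ± 0.628 (log2 change 0.68 ± 0.10 SE, adjusted p = 0.000736, 0.0714 over pair averages), and its change was −0.21 after median centring. CHLM, the methyltransferase of chlorophyll synthesis, read 0.211 ± 0.138 and 0.464 ± 0.0984 (adjusted p = 0.064), and 2 of the 2 measured members passed when adjusted over the list alone. For CHLM this held for the 12 arrays but not over pair averages (limma, adjusted p over the list alone 0.0874), and its change was −0.070 in the pair of arrays 1 and 2. No antioxidant enzyme passed in the planned fit, with or without adjustment over the list alone, though CCS passed on the deposited scale (log2 change 1.28, adjusted p = 0.0082) and SRX with a pseudocount (1.37, adjusted p = 0.0238). The peroxiredoxin PRXIIE read 0.157 ± 0.17 and 0.318 ± 0.0997 (adjusted p = 0.312), CCS, the copper chaperone of superoxide dismutase, 0.139 ± 0.0508 and 0.326 ± 0.068 (adjusted p = 0.311), and the sulfiredoxin SRX 0 to 0.304 and 0.357 to 0.554 (adjusted p = 0.202). GLDH, which carries out the last step of ascorbate synthesis, read 0.152 ± 0.15 and 0.435 ± 0.0913 (adjusted p = 0.0889), and APS4, an ATP sulfurylase of sulfate assimilation, 0.405 ± 0.122 and 0.382 ± 0.0871 (log2 change −0.87, adjusted p = 0.0504). APS4 passed over all genes in 8 of 16 other settings, such as loess and the pseudocount (adjusted p = 0.0135 to 0.0447), but not with the array number as a block (0.11), and on the deposited scale its change was −0.086 (adjusted p = 0.814). Each of these 2 was the single measured member of its list and passed when adjusted over that list alone, which is the unadjusted p of the 12-array limma fit (0.0307 and 0.0142). Over pair averages neither passed that way (limma, adjusted p over the list alone 0.0918 and 0.0763). The GLDH change was −0.22 in the pair of arrays 1 and 2, against 1.01 over all arrays.

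Subunits of the photosystems did not pass in the planned fit: PSBW read 71 ± 14.1 and 59.7 ± 20.9, PSBY 0.699 ± 0.0633 and 0.727 ± 0.0563, PSAN 0.365 ± 0.18 and 0.557 ± 0.0539, and the light-harvesting gene LHB1B2 1.22 ± 0.16 and 1.29 ± 0.0839 (adjusted p-values 0.196, 0.266, 0.612 and 0.824). In the Calvin cycle, PRK, the phosphoribulokinase, read 0.512 ± 0.167 and 0.565 ± 0.0843 (adjusted p = 0.14), and SBPASE was listed at 0 on all 12 arrays. The thioredoxin reductase NTRC read 0.32 ± 0.115 and 0.391 ± 0.0732 (adjusted p = 0.258), and FTRB, a subunit of ferredoxin-thioredoxin reductase, 0.082 ± 0.0197 and 0.149 ± 0.0473 (adjusted p = 0.563). For PRK, PSBY, NTRC and FTRB the log2 change after normalization was negative (−0.31, −0.31, −0.49 and −0.72) although the deposited level was higher with ascorbate, and for PSBW it was positive (0.16) although the level was lower. PSBW was among the brightest features, where normalized values reflect rank. Arrays 5 and 6 of both groups took 5.87, though PSBW read 60.4 and 58.2 with staurosporine and 34.3 and 37.2 with ascorbate. Its log2 change and p thus do not measure its change in level. None of these lists had a member that passed when adjusted over the list alone.

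Over all 3438 features, 480 were higher and 486 lower with ascorbate (limma, adjusted p under 0.05), of which 111 and 94 were among the 690 named genes. Taking each pair as 1 sample left 31 higher and 22 lower, 52 of them among the 966 features of the 12-array fit, and adding the pair as a block left 1 feature. That feature, probe 2399, has no gene listed. It read 0 on all 6 staurosporine arrays and 0.527 ± 0.076 with ascorbate (adjusted p = 6.2e-17, 4.8e-06 over pair averages, 0.0146 with the pair as a block). Its 6 staurosporine readings were all set to the floor and show no spread, so these p-values rest in part on the floor. Its log2 change was 11.3 in the planned fit and 3.41 with a pseudocount. Quantile normalization gives every array the same distribution of values. The near-even split of 480 and 486 is therefore largely set by the method and is no sign of a balanced response. Without normalization the split was 1093 higher and 208 lower (84.0% higher against 49.7%), and the median change over all features was 0.72 on the log2 scale. These 1093 include all 112 features listed at 0 on every array, because a zero takes the smallest positive value of its array and these values were on average higher on the ascorbate arrays. Among the 2540 features with no zero the split was 894 higher and 219 lower (80.3% higher), with a median change of 0.49. No label says that arrays of a group came from separate plants or cultures, so the p-values measure the spread between arrays, which may be technical.

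**Figure D3:**
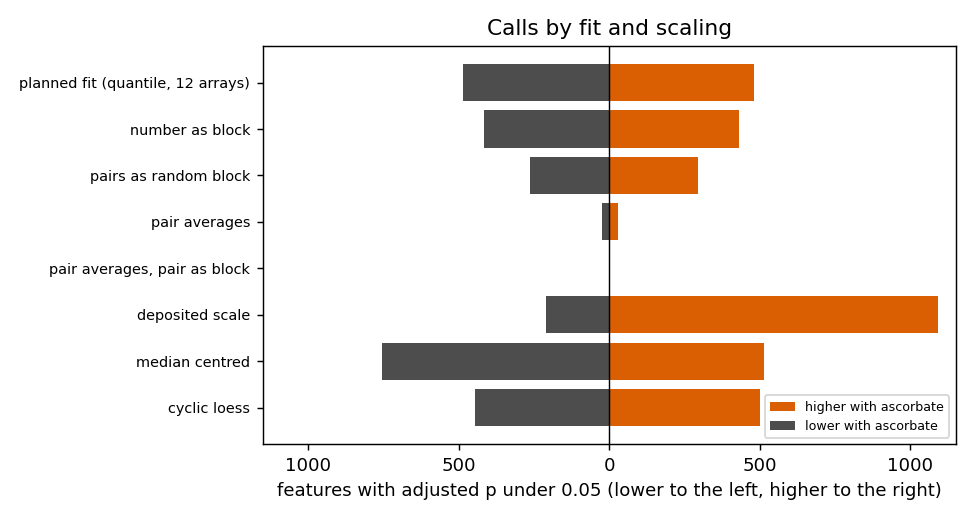
Number of features with an adjusted p under 0.05 (horizontal axis) by fit and scaling, with features higher with ascorbate to the right (orange) and lower to the left (grey). The planned fit gave 480 higher and 486 lower, pair averages 31 and 22, and the deposited scale 1093 and 208, where 112 of the 1093 were features listed at 0 on all arrays.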

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

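The tests of how consecutive and same-numbered arrays relate, and the tests of the intensity trend and of zeros, were chosen after the result was seen. The tests on brighter features and on other splits of the arrays were set before. The 3 patterns that follow concern the whole comparison, and the single readings after them are values that stood apart within a group of 6.

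Consecutive arrays of a group resembled each other: the closest array in the group carried the consecutive number for 12 of 12 arrays. This is consistent with repeat readings of 1 sample, which would leave 3 samples per group. For ascorbate arrays 3 and 4 the margin was narrow, with a Spearman correlation of 0.8894 to each other against 0.8862 and 0.8887 to the next array. The median SD within a pair was 0.151 (staurosporine) and 0.28 (ascorbate) on the log2 scale, against 0.344 and 0.367 between pair averages. Separate plants handled together may give the same closeness, and this was not tested.

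Same-numbered arrays also deviated together across the groups. If each array number stood for a filter or spot copy shared by the groups, the difference between the arrays of a pair should correlate between the groups. It did for numbers 1 to 4, with a lower correlation of 0.305 across features, and a shared copy may account for those. For numbers 5 and 6 the correlation was 0.0368, which argues against a strong effect specific to each number there. An effect common to both arrays of a pair cancels in the difference, so the test cannot decide on it. A filter that held both arrays of a pair, or a shared growth or hybridization batch, stays open.

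On the deposited scale most calls were higher with ascorbate (1093 against 208), and 112 of the higher ones were features at 0 on every array, which differed only through the smallest positive value set for zeros. Neither such values alone nor dim features alone gave the lean, since 80.3% of calls were higher among features without zeros (894 higher, 219 lower) and 70.8% among the brighter features (522 higher, 215 lower). The share over all features was 84.0%, so both may have added to the lean. The change fell with brightness (Spearman rho −0.468 across features without zeros, which are not independent), and array medians differed by 0.147, 1.04 and 1.09 log2 units between the groups in the 3 pairs. An intensity-dependent difference between arrays is a candidate explanation. A true rise of many weakly expressed transcripts after ascorbate stays open and untested.

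Of 100 splits of the 12 arrays drawn from 462, 1, the real one, gave as many calls as 966. The highest other split gave 19. Only 3 of the drawn splits, the real one among them, kept all 6 consecutive pairs whole. The draw treats the 12 arrays as independent, and consecutive arrays were correlated, so it cannot exclude chance for that count. The other split with 19 calls kept all 6 consecutive pairs whole. Among the 8 drawn splits that, like the real one, parted all 6 same-numbered pairs, the highest count after the real one was 0. Those other splits differed from the real one in separating consecutive arrays. For pair averages, 1 of the 10 splits, the real one, gave 53 calls, the highest other gave 3, and 10 splits are too few for a share under 0.05. For the plastid ribosomal proteins, 75 of 100 splits gave a camera p as small as 0.763, the smallest being 0.00749, so chance cannot be excluded.

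In 98 groups of 6 readings, 10 had 1 array apart from the others, where chance sets apart about 1 in 20 if readings are independent and continuous. Consecutive arrays were correlated and several readings were tied at the floor, so no excess is read from the 10. On the normalized log2 scale, AT1G56460 read −5.48 on staurosporine array 5, against −12.55 on the others, which were at 0. SRX read −12.55 (listed at 0) on staurosporine array 6, and AT4G32340 read −0.38 on staurosporine array 3, above the other 5. Among ascorbate arrays, array 1 was low for AT4G31210 (−3.88), AT2G33180 (−1.78) and AT4G01810 (−5.46). GLDH was low on array 2 (−2.92), PRXIIE on array 3 (−3.04) and AT4G37420 on array 5 (−3.57). AT5G27560 was listed at 0 on array 4 (−12.55).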

How the results depend on the processing

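The alternatives chosen after seeing the data were the removal of features at 0 or 100, pair averages with the pair as a block or with a pseudocount, the removal of arrays 1 and 2, and the removal of features with a zero on the deposited and median-centred scales. The count of 966 (480 higher, 486 lower) depended most on how consecutive arrays were treated. As a random block they gave 558 (296 higher, 262 lower) and ended 18 of 35 named calls, among them FATB (adjusted p = 0.252), AEF1 (0.133), AT1G29070 (0.0662), AT4G05030 (0.0597), AT5G27560 (0.122), RPL29 (0.0747), RPS10 (0.217) and AT1G68660 (0.062); averaging ended 27 of 35. The count was, averaged, 53 (31 and 22; 845 at an unadjusted p under 0.05), averaged with a pseudocount 161 (80 and 81), and averaged with the pair as a replicate block 1 (1 higher and 0 lower by limma; 713 at an unadjusted p under 0.05). The 3 pair averages per group leave fewer samples. The array number as a replicate block gave 849 (432 and 417), of which 742 were among the 966, and ended 11 of 35 named calls, of which AT1G67930 (adjusted p = 0.0612), AT3G49740 (0.0856), AT4G32340 (0.0525), AGL54 (0.0686) and AT2G33180 (0.1) are given here and the others in the report; among the genes chosen by rule or as zero-free it changed no other call, and it also ended those of AT1G61990 and AT3G13150. The deposited scale gave 1093 higher and 208 lower, ended 10 named calls without a change of sign besides that of RPS10, and added 4 (CCS, GLDH, PSAN and CHLM), and median centring gave 515 and 755 (40.6% higher) and ended 2 (RPS10, adjusted p = 0.178, and AT5G27560, 0.0625) without a change of sign. On both scales the higher calls include the 112 features at 0 on every array, SBPASE among them, which differ only by the floor of each array; without features that have a zero the splits were 894 and 219, and 358 and 829 (30.2% higher), and FTRB passed on the first scale (adjusted p = 0.0493) and GLDH (0.0271), PSBW (0.0292) and PSBY (0.0351) on the second. Loess, the pseudocount, removal of the dimmest 25%, the intensity trend, array weights, removal of features at 0 or 100 and removal of arrays 1 and 2 gave totals of 947, 1127, 994, 1023, 1013, 1009 and 846. Loess ended 2 named calls (AT1G58230, adjusted p = 0.0622, and AT1G11820, 0.0649), the pseudocount 1 (GH9B8, 0.0565), the intensity trend 1 (RPS10, 0.0608) and removal of arrays 1 and 2 ended 9 and added GLDH (0.019) and CHLM (0.0351). Without each array in turn the total was 793 to 953 (405 to 479 higher, 388 to 498 lower), 24 of 35 named calls held throughout and 11 were lost without at least 1 array. In 6 cases a named gene that did not pass in the planned fit passed when 1 array was left out. The ribosomal list did not pass under any camera setting (0 to 0 lists without each array in turn), and 1 list passed by limma's mixed fry test (adjusted p = 0.0315); it fell under 5 members without dim features or zeros, and was not run with the random block or the blocked pair averages. Log2 changes turned sign on the deposited scale for PRK (0.21), PSBW (−0.30), PSBY (0.043), RPS10 (0.17), NTRC (0.30) and FTRB (0.96), and after median centring for LHB1B2 (−0.68), PSAN (−0.046), PSBW (−1.06), RPL29 (−0.30), CHLP (−0.21) and FTRB (0.20). LHB1B2 also turned without arrays 1 and 2 (−0.11), and ran from −0.029 to 0.14 without each array in turn. The cause was not tested for these turns, and signal over background is not given in the sources used here, which limits what can be said of the dim genes.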

Other observations

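The gene groups described here were assembled, and their tests chosen, after the values were seen. Among 16 measured enzymes of plastid biosynthesis, 4 rose and 4 fell. The risers included SIRB (AT1G50170), the ferrochelatase of siroheme synthesis, from 0.184 ± 0.136 to 0.766 ± 0.208 (SD, n = 3 pair averages; adjusted p = 0.000458, 0.0831 over pair averages). KARI (AT3G58610), an enzyme of branched-chain amino acid synthesis, rose from 0.436 ± 0.0316 to 1.13 ± 0.0917 (adjusted p = 0.00269, 0.122 over pair averages). NADP-MDH (AT5G58330), the chloroplast malate dehydrogenase, rose from 0.166 ± 0.123 to 0.621 ± 0.0899 (adjusted p = 0.0182, 0.205 over pair averages). CHLP was the remaining riser, with the change of sign after median centring given above. Besides HISN4 and FATB, VTE6 (AT1G78620), the phytyl phosphate kinase of tocopherol synthesis, fell from 1.46 ± 0.197 to 0.638 ± 0.329 (adjusted p = 0.0019, 0.108 over pair averages). PPDK (AT4G15530), the pyruvate phosphate dikinase, fell by 0.59 on the log2 scale (adjusted p = 0.0453, 0.156 over pair averages), and its change was 0.0048, of the other sign, on the deposited scale.

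Of 15 measured genes of the photosynthetic apparatus, RIQ2 and PIFI rose, and PYG7 (AT1G22700), an assembly factor of photosystem I, fell from 1.34 ± 0.191 to 0.706 ± 0.0246 (adjusted p = 1.7e-05, 0.0445 over pair averages). The 15, and the tests of the photosynthetic group below, include SBPASE, which was listed at 0 on every array. Of 23 pentatricopeptide repeat and mTERF proteins, which process RNA or act on transcripts in organelles, 2 rose and 4 fell. AT1G61990 and AT3G13150 rose (adjusted p = 0.0263 and 0.0201, 0.0765 and 0.0779 with the array number as a block, and 0.188 and 0.182 over pair averages), and AEF1 and AT3G49740 were among those that fell. The AT3G49740 call (adjusted p = 0.0415) ended with the array number as a block (0.0856), over pair averages (0.267) and without any of 9 single arrays. AT3G51320 fell from 2.61 ± 0.17 to 1.33 ± 0.174 (adjusted p = 1.8e-05, 0.0445 over pair averages), and AT1G31790 fell by 1.24 on the log2 scale (adjusted p = 0.00156, 0.0565 over pair averages). Of 8 floral and meristem regulators, 2 rose: the MADS-box gene AGL54 (adjusted p = 0.014, 0.0686 with the array number as a block, 0.173 over pair averages) and the GRAS gene LAS (adjusted p = 0.0102, 0.179 over pair averages), so neither passed over pair averages. None of the 4 groups was shifted relative to other genes (camera adjusted p = 0.865 for each, and 0.902 with an estimated correlation). By limma's fry no group had a common direction (adjusted p = 0.763 for the enzymes, 0.688 for the photosynthetic, 0.55 for the organelle RNA and 0.571 for the floral group). Its mixed test, which asks whether members change in either direction, gave adjusted p-values of 3.2e-11, 3.5e-12, 3.4e-12 and 0.0477 in that order over the 12 arrays, and 1.8e-05, 3.7e-05, 0.000151 and 0.353 over pair averages. Since 205 of the 690 named genes passed and the groups were assembled after the values were seen, small values of the mixed test say nothing particular to these groups. The organelle RNA group had a median log2 change of 0.13 while camera ranked it lower, and the floral group a median of −0.013 and a mean of 0.15.

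Of the 690 named genes, 6 rose and 10 fell over pair averages, and none of the 16 passed with the pair as a block (limma, adjusted p = 0.196 for each; 713 of all features had an unadjusted p under 0.05). Those not described so far were AT3G45770 (from 0.15 ± 0.0701 to 0.535 ± 0.0541), AT4G23110 (0.211 ± 0.128 to 0.78 ± 0.019), AT4G30150 (0.238 ± 0.135 to 0.814 ± 0.122) and AT5G05400 (0.144 ± 0.0619 to 0.573 ± 0.116), which rose. AT4G22650 (1 ± 0.235 to 0.422 ± 0.0592), AT3G57120 (0.729 ± 0.264 to 0.376 ± 0.0477) and AT5G49120 (0.756 ± 0.225 to 0.483 ± 0.0533) fell.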
